A study of Mus musculus with 48 samples.

How the data were processed

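Liver mRNA was sequenced from 48 male C57BL/6 mice aged 4 to 6 months. The KO mice carried floxed alleles of Bmal1 (Arntl in the gene table) and a ubiquitous Cre recombinase that tamoxifen activates; the control mice, called WT in the labels, were littermates with the floxed alleles and no Cre. Both genotypes received 5 mg of tamoxifen per day by gavage for 5 days. After 7 further days the mice spent 36 h in constant darkness and were killed in darkness every 4 h over 20 h, with 4 mice per genotype and time, which makes 12 groups of 4. Times are given as zeitgeber hours (ZT), as the labels have them. Every KO mouse carried Cre and no WT mouse did, so an effect of Cre itself cannot be separated from the loss of Bmal1. The labels give each mouse's body weight and housing: 38 mice were group-housed in 19 cages, 11 of which held both genotypes, and 10 lived alone. Cage letters show that the mice of ZT4 and ZT8, those of ZT12 and ZT16, and those of ZT20 and ZT0 came from different cage sets, so cage set and time of day are confounded, while each set held both genotypes in equal number. The numbers of the mice do not pair them across groups, but the 11 mixed cages tie WT and KO mice killed at the same time. The main models left this tie out, and no paired analysis was made. Cage entered only as a random block, among the alternatives.

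Poly-A RNA was made into libraries with a kit that does not record the strand, amplified over 13 PCR cycles and sequenced with 2 libraries per lane. Per the labels, the authors called bases with CASAVA (version not given) and aligned reads with STAR 2.4.0f1 to mouse genome build mm9. The deposited table holds whole-number read counts for 23732 genes in 48 libraries. How reads that match several genes were handled and which gene models were used are not stated. Total counts per library lay between 33562272 and 34035644 (median 33855278), with a spread of 0.302% of the mean, so the authors brought the libraries to a common depth before deposit by a step that is not described. The number of reads sequenced per library is therefore unknown. At this depth replicates differ by more than counting error over all genes, while for named genes far under 1 CPM, such as Ncr1 and Npas2 in WT at ZT12, counting error is much of the spread. No identical libraries were found: counts of replicate pairs differed by 28.2 to 160 times the variance of counting alone. Sequencing reads without molecular identifiers are not independent molecules.

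Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), which left 14836 genes with 99.975% of all counts, and libraries were scaled by TMM factors (0.898 to 1.14). A quasi-likelihood model with 1 mean per group (36 residual degrees of freedom) gave KO minus WT averaged over the 6 times (the mean of 6 log2 fold changes, which can differ from the ratio of mean CPM), KO minus WT at each time, and the genotype by time interaction (5 degrees of freedom). A model with a 24 h cosine and sine per genotype (42 residual degrees of freedom) gave the rhythm in WT, the rhythm in KO (2 degrees of freedom each) and the difference between them. Its amplitude is the fitted distance from the mean to the peak on the log2 scale. Adjusted p values are Benjamini-Hochberg values over all genes tested, and genes with an adjusted p under 0.05 are called. Standard errors (SE) of log2 fold changes and amplitudes were derived from the F statistics; those of amplitudes are approximate. Levels are CPM (edgeR's cpm function) with TMM scaling, given as mean and SD over mice; log2 CPM used a prior count of 2. The 24 h fit rests on 1 cycle sampled at 6 times.

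Gene lists for pathways and cell types, 40 in number, were compiled beforehand, and 39 had enough measured members for camera (limma 3.58.1, preset correlation 0.01). camera was repeated with an estimated correlation, and fry asked whether a list's members moved, on balance, one way. Counts of called members are given over all genes and adjusted over the list alone. Shares of WT-rhythmic members were compared with other genes by two-sided Fisher's exact tests. These take the members of a list as independent, so their p values can be too small where members move together across the same mice. Body weights were compared by a two-sided permutation test within times. Correlations across mice have two-sided permutation p values, adjusted over the 9 relations computed.

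Named genes are Arntl and the members of the E-box and REV-ERB clock lists; the 10 largest rises and 10 largest falls averaged over times among called genes with at least 5 CPM and the same sign at all 6 times; the 3 largest of each direction at each time with at least 5 CPM and not named by those rules; the 10 smallest p values of the interaction and of the rhythm difference; the 10 largest amplitudes in each genotype at 5 CPM or more and the 10 smallest p values in KO; and up to 4 members of each list per test. Predicted genes were skipped. These rules, the lists, the tests and most alternatives were fixed before the data were examined. Baat, Scd1, Selenbp2, Mt1, Cox8a, Cyp17a1, Prlr and Trim24 fall outside the rules and were named after their values were seen.

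Alternatives were DESeq2 size factors or total counts in place of TMM, no filter or a filter of 1 CPM in 4 libraries, limma-voom, DESeq2 1.42.0, housing, body weight or cage (as a random block) in the model, only the 8 libraries of a time or the 24 of a genotype, a change of at least 2-fold, 6 time means or 24 h and 12 h cosines for rhythms, a peak at least 1.5 times the trough, and each mouse left out in turn. Without the 4 libraries farthest from their groups, and with each library's gene length trend in the model (transcript lengths of 14413 genes, 97.1% of those tested), were added after the data were seen. In counts simulated with the means and spreads of these libraries, edgeR found at ZT0 40% of genes changed 1.5-fold and 86% of those changed by 2-fold; averaged over times it found 92% and 96%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.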

Results

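Liver transcripts were counted in 24 WT and 24 KO mice, 4 of each genotype at each of 6 times (ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20) in constant darkness. BMAL1, the product of Arntl, pairs with CLOCK or NPAS2 and activates genes through E-box elements; it was deleted in adult mice, so that the effect of its loss could be seen apart from its role in development. Each library held 33562272 to 34035644 counts, and 17690 to 18774 genes had at least 1 count in a library. The most abundant gene took 1.45 to 2.61% of a library's counts. The mean correlation of a library with the others of its group was 0.974 to 0.990, and the first 2 principal components carried 13.2% and 10.2% of the variance. The libraries farthest from their groups were KO mice 20 and 21 of ZT12 and KO mice 43 and 44 of ZT0. KO mouse 21 of ZT12 also had the lowest trend of expression with transcript length (-0.316, against -0.0843 to 0.135 in the other libraries). Body weight, measured once per mouse, was 30.5 g ± 2.08 (SD, n = 24) in WT and 27.9 g ± 2.52 (SD, n = 24) in KO. The difference of -2.54 g (-8.34%) had the same sign at all 6 times (permutation p = 0.00073).

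The targeted gene, Arntl (ENSMUSG00000055116, mm9 chromosome 7, 120350979 to 120457636), cycled in WT liver and stayed near an intermediate level in KO liver. In WT mice its level was 39.4 CPM ± 5.54 at ZT0, 18.2 ± 8.54 at ZT4, 1.35 ± 0.349 at ZT8, 6.93 ± 5.03 at ZT12, 31.3 ± 7.02 at ZT16 and 43.9 ± 3.67 at ZT20 (SD, n = 4 each). In KO mice it was 14.9 CPM ± 9.92, 13.4 ± 6.10, 12.7 ± 7.14, 17.9 ± 4.37, 16.4 ± 6.90 and 10.1 ± 5.05 at the same times (SD, n = 4 each). Arntl was therefore higher in KO at ZT8 (log2 fold change 3.23 ± 0.56 SE, adjusted p = 0.000235) and lower at ZT20 (-2.12 ± 0.49 SE, adjusted p = 0.0196). The call at ZT20 ended without KO mouse 38 (adjusted p = 0.0917). The mean of its 6 log2 fold changes was -0.05 ± 0.20 (SE, adjusted p = 0.916), with 23.5 CPM ± 17.04 in WT and 14.2 ± 6.57 in KO over all times (SD, n = 24 each). The floxed allele removes only part of the gene, so counts over the whole gene do not check the deletion. In WT the fitted 24 h wave of Arntl had a log2 amplitude of 2.03 ± 0.27 (SE; 16.6-fold from trough to peak) with its peak at ZT 21. In KO the amplitude was 0.18 (adjusted p = 0.833 for a rhythm).

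Group means of genes driven through E-boxes swung less in KO and stayed between the WT extremes. Dbp (ENSMUSG00000059824, chromosome 7, 52960458 to 52965525), a transcription factor at the output of the clock, ran in WT from 0.973 CPM ± 0.740 at ZT0 to 146 ± 6.02 at ZT8 (SD, n = 4 each). In KO its group means stayed between 6.86 CPM at ZT12 and 28.2 CPM at ZT20. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98629246 to 98636647), which encodes the repressor REV-ERBα, ran in WT from 2.37 CPM ± 0.849 at ZT16 to 135 ± 13.2 at ZT4 (SD, n = 4 each), and in KO between 13.3 and 37.3 CPM. The fitted WT waves spanned 123-fold for Dbp (peak at ZT 8.36), 69.0-fold for Nr1d1 (ZT 5.58), 102-fold for Gm129 (ZT 10.1), 10.5-fold for Per2 (ZT 13.6) and 12.7-fold for Per1 (ZT 11.6). Over the 15 E-box targets the median log2 amplitude was 1.52 in WT and 0.358 in KO; all 15 were rhythmic in WT, none were called in KO, and the rhythm differed between genotypes for all 15.

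Group means of genes that REV-ERB proteins repress were flatter too. Npas2 (ENSMUSG00000026077, chromosome 1, 39250576 to 39420079), a partner of BMAL1, fell in WT from 14.8 CPM ± 3.61 at ZT0 to 0.0678 ± 0.0462 at ZT12 (SD, n = 4 each). In KO mice Npas2 stood at 11.3 CPM ± 8.54 at ZT12 (SD, n = 4, adjusted p = 1.51e-06). The mean of its 6 log2 fold changes was 1.90 ± 0.30 (SE, adjusted p = 3.19e-05), raised by ZT8 and ZT12 (4.90 and 7.31), where WT was under 1 CPM. Over all times Npas2 stood at 5.57 CPM ± 6.58 in WT and 7.07 ± 6.20 in KO (SD, n = 24 each). At ZT8 all 5 REV-ERB-repressed genes were higher in KO: Arntl, Npas2, Clock by 0.74 (adjusted p = 0.04), Cry1 by 1.40 (adjusted p = 0.0192) and Nfil3 by 1.63 (adjusted p = 0.000184) on the log2 scale. The median amplitude of these 5 genes was 1.48 in WT and 0.188 in KO, and the rhythm differed between genotypes for each. Npas2 alone was called rhythmic in KO (amplitude 1.19 ± 0.27 SE, peak at ZT 15.6, adjusted p = 0.0427), with its WT peak at ZT 22.3. Of 8 other clock components, 5 were rhythmic in WT, and the rhythm differed for 1. Fbxl21 rose on average (0.20 ± 0.05 SE, adjusted p = 0.0122; adjusted over the list alone, 1 higher and 0 lower; not called with body weight in the model).

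**Figure D1:**
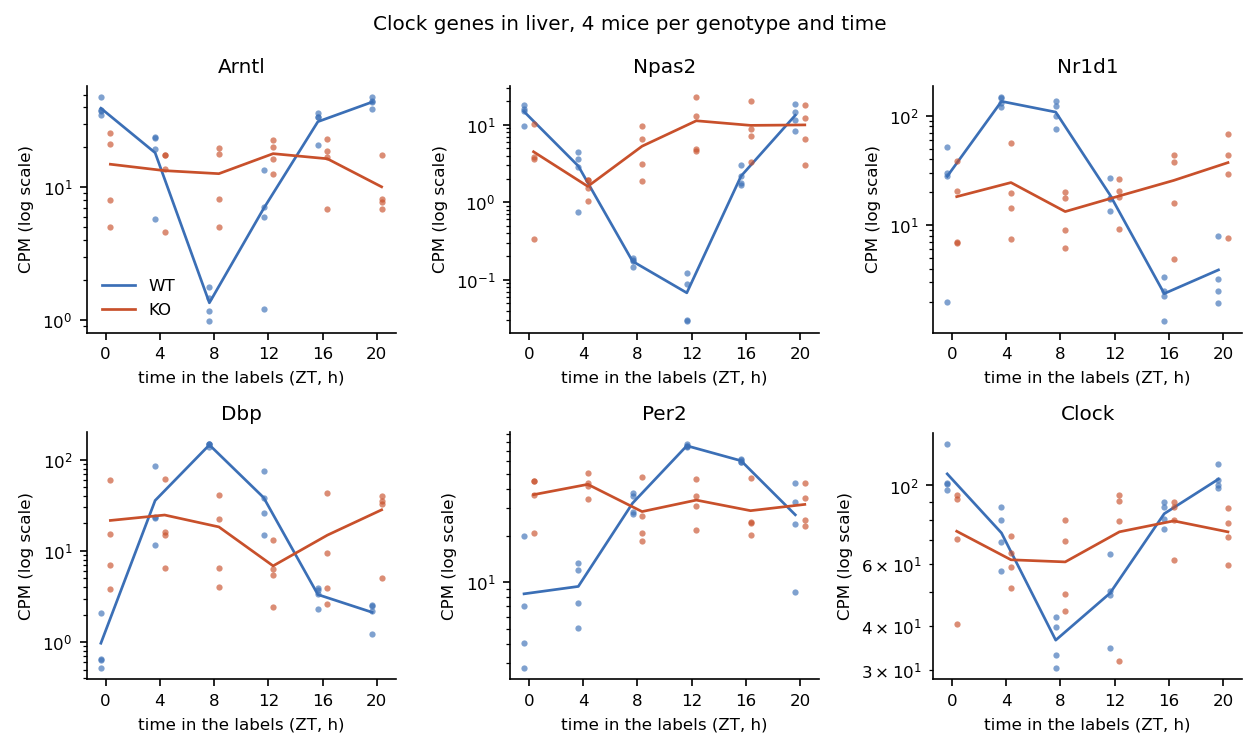
Levels of Arntl, Npas2, Nr1d1, Dbp, Per2 and Clock in CPM (log axis) against the time of death in hours, with 1 point per mouse (n = 4 per genotype and time), blue for WT and orange-red for KO, and lines through the group means. WT Dbp rises to 146 CPM at ZT8 while KO means stay between 6.86 and 28.2 CPM, and KO Arntl means stay between 10.1 and 17.9 CPM.

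The individual KO mice of a group differed from each other in where their clock genes stood. Projected on the WT waves of the 20 clock genes, WT mice lay 0.86 to 1.39 times the fitted wave from the centre (median 1.097), and 23 of 24 pointed within 3 h of their label. WT mouse 42 of ZT0 pointed to -4.01 h from it. The waves were fitted to these same WT mice, so the place of WT mice is partly built in. Levels were also centred on each genotype's own gene means before the projection. KO positions therefore average to the centre by construction, and they do not give the mean KO level on the WT clock. The projection explained from 4.65% (KO mouse 21 of ZT12) to 97.2% (KO mouse 5 of ZT4) of a KO mouse's variance. KO mice lay at 0.1 to 0.73 (median 0.384), and 3 of 24 pointed within 3 h of their label. Among KO mice Arntl and Dbp ran opposite to each other, with r = -0.886 and rho = -0.843 over 24 mice on log2 CPM (both permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3e-05) and r = -0.847 without the 2 mice farthest out. Taken as deviations from group means, which also removes the cage sets, the relation was r = -0.876 and rho = -0.855 (both permutation p = 1e-05, adjusted p = 3e-05; r = -0.839 without 2). The 4 KO mice of ZT12, taken alone, did not run opposite in Arntl and Dbp. Arntl and Nr1d1 ran opposite as well (r = -0.677, permutation p = 0.00048, adjusted p = 0.00072; rho = -0.676, permutation p = 0.00043, adjusted p = 0.000645; r = -0.599 without 2).

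**Figure D2:**
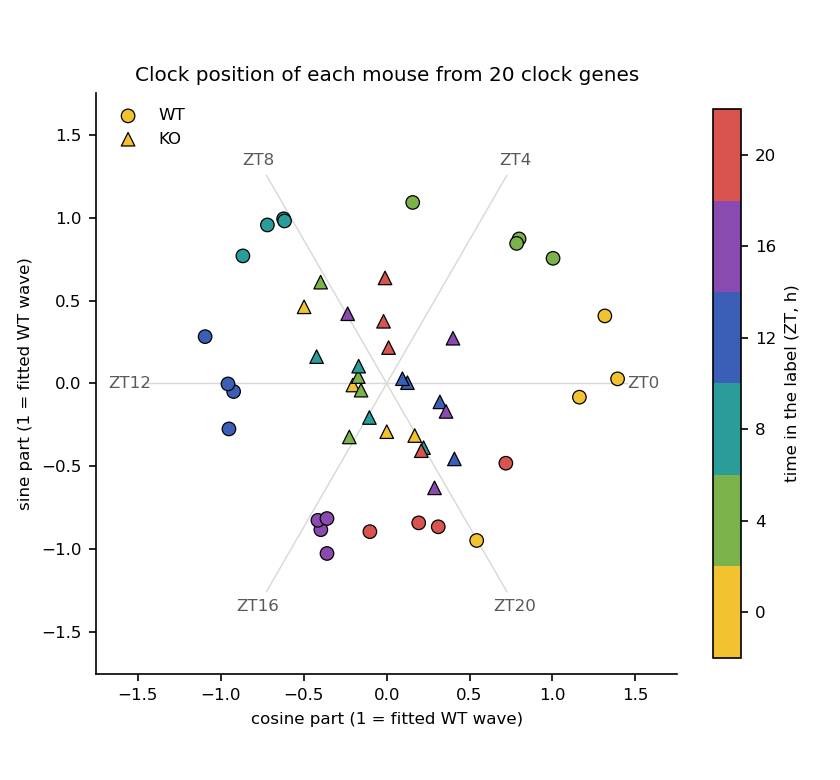
Position of each mouse relative to the mean of its own genotype, projected on the WT waves of 20 clock genes. The horizontal axis is the cosine part and the vertical axis the sine part, both in units of the fitted WT wave. Circles mark WT, triangles KO and colour the labelled time. WT mice, to which the waves were fitted, lie on a ring at 0.86 to 1.39, 23 of 24 within 3 h of their label. KO mice, centred on the KO mean, lie at 0.1 to 0.73.

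Averaged over the 6 times, several steroid-metabolising genes that female liver expresses more were higher in KO, and several genes of fatty acid oxidation lower. As lists these 2 groups were not called by camera with an estimated correlation (adjusted p = 0.284 and 0.0784). Among genes with at least 5 CPM and the same sign at all 6 times, the largest rises were in cytochrome P450 and sulfotransferase genes. Cyp3a41b (ENSMUSG00000075552, chromosome 5, 146319544 to 146345599) stood at 0.158 CPM ± 0.319 in WT and 10.7 ± 11.3 in KO, Cyp3a16 at 0.536 ± 0.899 and 37.6 ± 43.1, while Sult2a1 stood at 1.06 ± 1.29 and 12.3 ± 12.4 (SD, n = 24 each). Sult2a1 (ENSMUSG00000078798, chromosome 7, 14381601 to 14422759) sulfates steroids and bile acids. The log2 fold changes of these 3 genes were 6.66 ± 0.69, 6.30 ± 0.67 and 3.69 ± 0.48 (SE; adjusted p = 1.57e-08, 1.97e-08 and 9.05e-07). Cyp2c69, Slc22a26, Sult2a2, Cyp3a41a and Cyp3a44 rose by 1.44 to 3.49. Outside this group, Ly6a, a cell surface antigen, rose from 15.3 CPM ± 4.48 to 40.3 ± 18.6 (SD, n = 24 each; log2 1.36 ± 0.15 SE, adjusted p = 1.97e-08). Lpl, the lipase that hydrolyses lipoprotein triglyceride, rose from 47.8 CPM ± 21.8 to 120 ± 72.3 (SD, n = 24 each; log2 1.30 ± 0.15 SE, adjusted p = 1.54e-07).

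Among genes with at least 5 CPM and the same sign at all 6 times, the largest falls averaged over the 6 times were in Hsd17b6, Saa1, Hamp, Hspb1, Smad9, Id1, Cyp2u1, Cyp4a14, Serpine2 and Agxt2l1. Hsd17b6 (ENSMUSG00000025396, chromosome 10, 127427997 to 127437734), a steroid dehydrogenase, stood at 45.8 CPM ± 30.0 in WT and 12.5 ± 6.51 in KO (SD, n = 24 each; log2 -1.88 ± 0.25 SE, adjusted p = 1.17e-06). Hamp (ENSMUSG00000050440, chromosome 7, 31727390 to 31729036), which encodes the iron hormone hepcidin, stood at 586 CPM ± 259 and 261 ± 153 (SD, n = 24 each; log2 -1.17 ± 0.25 SE, adjusted p = 0.00164). Smad9 and Id1, components of bone morphogenetic protein signalling, changed by -0.92 ± 0.14 and -0.80 ± 0.16 (SE; adjusted p = 9.3e-06 and 0.00121), and Cyp4a14, a fatty acid hydroxylase, by -0.76 ± 0.20 (SE, adjusted p = 0.0118). Of the 20 genes named here as largest rises and falls, 19 kept an adjusted p under 0.05 whichever mouse was left out. Saa1 did not: its change of -1.44 ± 0.45 (SE, adjusted p = 0.0366) was -0.82 with an adjusted p of 0.193 without WT mouse 29 of ZT16. It was called in 36 of the 48 fits that left out 1 mouse.

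In all, 1314 of 14836 genes differed on average by edgeR, 733 higher and 581 lower in KO; 61 of them were at least 2-fold higher and 19 at least 2-fold lower. With total counts in place of TMM the split was 636 higher and 618 lower. With body weight in the model 711 genes were called, 657 of them among the 1314.

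Female-biased liver genes formed the group with the largest shift. Of 25 measured members 14 rose and 0 fell, with a median log2 fold change of 0.97 (adjusted over the list alone, 18 higher and 0 lower). camera gave an adjusted p of 1.27e-12, and adjusted p = 0.284 with an estimated correlation. Without the 4 libraries farthest from their groups 16 rose, and with body weight in the model 12. Many members belong to families of near-identical genes (Cyp3a, Cyp2c, Sult2a), among which reads can be shared. Of 24 male-biased genes, Hsd3b5 rose (1.86 ± 0.50 SE, adjusted p = 0.0143) while Selenbp2, Cyp2u1, Cspg5 and Gstp1 fell by 1.01, 0.79, 0.79 and 0.37 (adjusted over the list alone, 1 higher and 5 lower). The median of the list was -0.17 (camera adjusted p = 0.0265, adjusted p = 0.835 with an estimated correlation). The 4 falls were 1 with body weight in the model, 2 with the length trend, 6 without the 4 farthest libraries, where Hsd3b5 was not called, and 2 to 6 when 1 mouse was left out. Cspg5 was not called without WT mouse 35 of ZT20 (adjusted p = 0.0878). The mean log2 CPM of the male-biased and the female-biased list ran opposite across the 24 mice of each genotype. In KO r was -0.924 and rho -0.872 (both permutation p = 1e-05, adjusted p = 3e-05). In WT r was -0.839 and rho -0.821 (both permutation p = 2e-05, adjusted p = 4.5e-05). Without the 2 mice farthest out r was -0.914 in KO and -0.809 in WT.

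Among 29 genes of xenobiotic metabolism 6 rose and 2 fell (adjusted over the list alone, also 6 and 2; camera adjusted p = 0.13). With body weight in the model 4 were higher and 3 lower, and when 1 mouse was left out 6 to 7 were higher and 1 to 3 lower. Gstm1 rose by 0.57 (adjusted p = 0.000194), Cyp2c50 by 0.53 (adjusted p = 1.91e-05) and Sult1d1 by 0.53 (adjusted p = 5.69e-06), and the glutathione transferase gene Gstt2 changed by -0.70 ± 0.08 (SE, adjusted p = 5.91e-08). NRF2 targets, which respond to oxidants, had 6 of 23 members higher and 0 lower, the same count adjusted over the list alone. Gstm3 rose from 71.8 CPM ± 22.9 to 189.6 ± 112 (SD, n = 24 each; log2 1.34 ± 0.16 SE, adjusted p = 1.87e-07) and Gstm2 by 0.995 ± 0.109 (SE, adjusted p = 3.41e-08). Reads can be shared among the Gstm genes, which make 3 of the 6 calls. Gstm1, Prdx1, Gsta3 and 1 more rose too (camera adjusted p = 0.0469, adjusted p = 0.835 with an estimated correlation). In bile acid synthesis and transport 4 of 22 genes rose (Akr1d1 by 0.31, Akr1c6 by 0.24, Acox2 by 0.21 and Baat by 0.09). Cyp8b1, the sterol hydroxylase that sets the cholic acid share, changed by -0.67 ± 0.17 (SE, adjusted p = 0.00833). Adjusted over the list alone, 8 were higher and 1 lower (camera adjusted p = 0.0496, adjusted p = 0.835 with an estimated correlation). The 4 rises were 2 with body weight in the model, 2 beside 2 falls without the 4 farthest libraries, and 2 to 5 when 1 mouse was left out. Acox2 was not called without KO mouse 39 of ZT20 (adjusted p = 0.0583), nor Gsta3 without KO mouse 30 of ZT16 (adjusted p = 0.0716).

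Genes of fatty acid oxidation and targets of the nuclear receptor PPARA were lower on average where called. Of 25 members 13 were lower in KO and 0 higher, with a median log2 fold change of -0.19 (adjusted over the list alone, 0 higher and 17 lower). camera gave an adjusted p of 1.27e-12, and adjusted p = 0.0784 with an estimated correlation; fry gave an adjusted p of 2.76e-05. Besides Cyp4a14, Vnn1 changed by -0.53 ± 0.09 (SE, adjusted p = 4.75e-05) and the fatty acid binding protein gene Fabp1 by -0.39 ± 0.07 (SE, adjusted p = 0.000112). The lipid droplet gene Plin2 changed by -0.35 ± 0.06 (SE, adjusted p = 0.000157) and Hadhb by -0.21 ± 0.04 (SE, adjusted p = 0.000134). In fatty acid synthesis 2 of 23 genes rose (Thrsp by 0.61, adjusted p = 0.0209, and Pklr by 0.56, adjusted p = 0.00405). Scd1, Fads2 and Elovl5 fell by 0.34, 0.26 and 0.25 (adjusted over the list alone, 4 higher and 3 lower; camera adjusted p = 0.821). With body weight in the model neither rise was called, and with the length trend 1 gene was lower. Without the 4 farthest libraries 3 were higher and 0 lower by edgeR, and when 1 mouse was left out 2 to 4 were higher. None of 24 genes of cholesterol synthesis and uptake passed by edgeR on average, over all genes or adjusted over the list alone (median 0.14; camera adjusted p = 0.0469, adjusted p = 0.835 with an estimated correlation).

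Glucose metabolism changed in both directions, with 5 of 20 genes higher and 4 lower, the same counts adjusted over the list alone (camera adjusted p = 0.474). The 4 falls were 2 with the length trend in the model, and 2 to 4 when 1 mouse was left out. Gys2 (ENSMUSG00000030244, chromosome 6, 142371133 to 142421629), the liver glycogen synthase, changed by -0.52 ± 0.06 (SE, adjusted p = 3.63e-08). Ppp1r3b, which directs phosphatase to glycogen, rose by 0.69 ± 0.12 (SE, adjusted p = 0.00014). Gckr, the regulator of glucokinase, rose by 0.32 ± 0.04 (SE, adjusted p = 1.89e-06) and Pygl by 0.27 ± 0.05 (SE, adjusted p = 0.000182). Of 26 genes of amino acid breakdown and the urea cycle, Prodh rose and Hal and Ass1 fell (by 0.21 and 0.19; adjusted over the list alone, 1 higher and 3 lower; camera adjusted p = 0.766). The falls numbered 0 to 4 when 1 mouse was left out. Without WT mouse 48 of ZT0 Hal had an adjusted p of 0.083, and without KO mouse 26 of ZT16 Ass1 had 0.0529. In NAD metabolism Acmsd and Qprt fell by 0.58 and 0.20 and 16 of 18 genes did not pass (adjusted over the list alone, 0 higher and 2 lower; camera adjusted p = 0.2). Neither was called with body weight in the model, nor was Prodh.

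Ribosomal protein genes were slightly higher in KO. Of 35 members 18 rose and 0 fell, with a median log2 fold change of 0.15 (adjusted over the list alone, 32 higher and 0 lower; camera adjusted p = 2.7e-16, adjusted p = 0.569 with an estimated correlation). Rpl7 rose by 0.22 ± 0.05 and Rpl4 by 0.19 ± 0.04 (SE; adjusted p = 0.00139 and 0.000622). The count was 6 without the 4 libraries farthest from their groups, 7 with body weight and 11 with the length trend in the model, and 15 to 26 when 1 mouse was left out. Oxidative phosphorylation had 0 of 34 members higher and 5 lower. These were Sdhd, Sdha, Cox8a, Ndufs1 and Atp5b, lower by 0.14, 0.13, 0.13, 0.11 and 0.10 (adjusted over the list alone, 0 higher and 8 lower; camera adjusted p = 0.000157, adjusted p = 0.835 with an estimated correlation). That count was 15 without the 4 farthest libraries and 18 with the length trend, and it ran from 2 to 9 when 1 mouse was left out. Ndufs1 was not called without WT mouse 42 of ZT0 (adjusted p = 0.0666), nor Atp5b without WT mouse 16 of ZT8 (adjusted p = 0.0715). Of 26 ribosome biogenesis genes Npm1 rose (0.14, adjusted p = 0.0307; adjusted over the list alone, 0 higher and 0 lower; camera adjusted p = 0.0688); without WT mouse 13 of ZT8 its adjusted p was 0.0538, and it was not called with body weight, with the length trend or without the 4 farthest libraries.

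Stress and signalling lists changed little on average. Of 20 heat shock genes Hspa8, Hsph1 and Dnaja1 rose (by 0.36, 0.34 and 0.19). The small heat shock gene Hspb1 changed by -0.95 ± 0.13 (SE, adjusted p = 4.24e-06; adjusted over the list alone, 5 higher and 1 lower; camera adjusted p = 0.456). The 3 heat shock rises were 1 with body weight and 1 with the length trend in the model, and 1 to 5 when 1 mouse was left out. Hsph1 and Dnaja1 were not called without KO mouse 44 of ZT0 (adjusted p = 0.0708) and KO mouse 26 of ZT16 (adjusted p = 0.0615). Rbm3, of 2 cold-inducible genes, rose by 0.34 ± 0.06 (SE, adjusted p = 0.000112; adjusted over the list alone, 1 higher; camera adjusted p = 0.0269, adjusted p = 0.284 with an estimated correlation). Trib3, of 24 unfolded protein response genes, changed by -0.94 ± 0.17 (SE, adjusted p = 0.000203; adjusted over the list alone, 0 higher and 1 lower; camera adjusted p = 0.456). Per1, Tsc22d3 and Sgk1 rose among 17 glucocorticoid targets (by 0.67, 0.44 and 0.19; adjusted over the list alone, 6 higher and 1 lower; camera adjusted p = 0.149). Ccne2 and Pcna rose among 30 cell cycle genes (by 0.41 and 0.17; adjusted over the list alone, also 2; camera adjusted p = 0.00847, adjusted p = 0.835 with an estimated correlation). Ddit4l and Phlda3 rose among 19 p53 targets (by 0.43 and 0.33; adjusted over the list alone, 3 higher; camera adjusted p = 0.404). With body weight in the model 1 cell cycle gene was higher, and 0 glucocorticoid targets were higher and 1 lower by edgeR. Of the glucocorticoid targets 1 was higher without the 4 farthest libraries, and 1 to 5 were higher when 1 mouse was left out. Sgk1 was not called without KO mouse 39 of ZT20 (adjusted p = 0.0562), nor Per1 without KO mouse 44 of ZT0 (adjusted p = 0.0525). None of 20 immediate early genes passed (adjusted over the list alone, 0; camera adjusted p = 0.501). Of the clock lists, Per1 and Per3 rose (by 0.67 and 0.59), Bhlhe41 changed by -0.67 ± 0.21 (SE, adjusted p = 0.0395). The other 12 E-box targets did not pass on average (adjusted over the list alone, 2 higher and 1 lower; camera adjusted p = 0.115). Per1 stood at 22.4 CPM in WT and 24.4 in KO over all times (means of 24 mice each). With body weight or the length trend in the model 0 E-box targets were called on average by edgeR, and 1 to 3 were higher when 1 mouse was left out. Per3 had an adjusted p of 0.0868 without KO mouse 26 of ZT16, and Bhlhe41 of 0.0888 without WT mouse 8 of ZT4. Npas2 alone passed among the 5 REV-ERB-repressed genes, also adjusted over the list alone (camera adjusted p = 0.461).

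In most inflammatory and cell type lists few members passed. Of 28 acute phase genes Hamp2, Mt1 and Cp rose by 1.17, 1.13 and 0.30. Saa2, Saa1 and Hamp changed by -2.01, -1.44 and -1.17 (adjusted over the list alone, 4 higher and 3 lower; camera adjusted p = 0.115). When 1 mouse was left out 3 to 7 were higher and 1 to 3 lower. Reads can be shared between Hamp and Hamp2 and between Saa1 and Saa2. Saa2 was spread widely in WT (677 CPM ± 1838, against 105 ± 77.7 in KO; SD, n = 24 each) and had an adjusted p of 0.091 without WT mouse 29 of ZT16. None of 29 interferon response genes, 16 antigen presentation genes or 16 stellate cell and fibroblast markers passed by edgeR, over all genes or over each list alone (camera adjusted p = 0.149, 0.466 and 0.821). None of 13 Kupffer cell markers passed over all genes, while 6 were higher adjusted over the list alone, 6 without the 4 farthest libraries and 0 to 6 by edgeR when 1 mouse was left out (median 0.19, camera adjusted p = 0.0197, adjusted p = 0.835 with an estimated correlation). Of 12 monocyte and dendritic cell markers Cx3cr1 and Fcgr4 rose (by 0.70 ± 0.14 and 0.42 ± 0.09 SE; adjusted over the list alone, 4 higher; camera adjusted p = 0.461; 2 to 4 higher when 1 mouse was left out). The median of 11 neutrophil markers was -0.44, with Camp and Ltf, both under 1 CPM, changed by -1.46 and -1.30 (adjusted over the list alone, 4 lower; camera adjusted p = 0.0269, adjusted p = 0.835 with an estimated correlation). Neither was called with body weight in the model or without the 4 farthest libraries, and 0 to 4 markers were lower when 1 mouse was left out. They were not called without WT mouse 45 of ZT0 (adjusted p = 0.103) and WT mouse 36 of ZT20 (adjusted p = 0.0885). Single markers changed in 3 more lists. Of 15 T and NK cell genes it was Ncr1 (-0.70; adjusted over the list alone, 0; camera adjusted p = 0.237; not called without WT mouse 11 of ZT8, adjusted p = 0.0904). Of 9 B and plasma cell genes it was Igj (-0.76; over the list alone, 1 lower; camera adjusted p = 0.363). Of 15 sinusoidal endothelial genes it was Kdr (-0.18; over the list alone, 1 lower; camera adjusted p = 0.404). Ncr1 and Igj were not called with body weight in the model, Ncr1 and Kdr not without the 4 farthest libraries, and Ncr1 not with the length trend.

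Of 13 hepatocyte markers Apoa1 and Ahsg rose by 0.33 and 0.29 (adjusted over the list alone, also 2; camera adjusted p = 0.456). Apoa1 was not called with body weight, with the length trend or without the 4 farthest libraries, and Cela2a, below, not with body weight. None of 7 erythroid or 10 cholangiocyte markers passed over all genes by edgeR (adjusted over the list alone, 0 higher and 1 lower, and 1 higher and 1 lower; camera adjusted p = 0.347 and 0.987). Adipose markers went both ways, Fabp4 up by 0.34 and Cidec changed by -0.77 of 4 (adjusted over the list alone, 1 and 1; camera adjusted p = 0.789). Of 2 pancreas markers Cela2a, at 0.352 CPM in WT and 0.486 in KO, rose by 0.64 (adjusted over the list alone, 2 higher; camera adjusted p = 0.0269, adjusted p = 0.179 with an estimated correlation). The muscle list had 1 measured member, Mylpf, which did not pass. camera called 13 of 39 lists, 9 up and 4 down, and 0 with an estimated correlation, where 4 lists had an unadjusted p under 0.05; fry called 5. For fatty acid synthesis, amino acid breakdown, acute phase genes, monocyte and dendritic cell markers, and stellate cell markers, the sign of the list's median and the direction of camera differed.

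**Figure D3:**
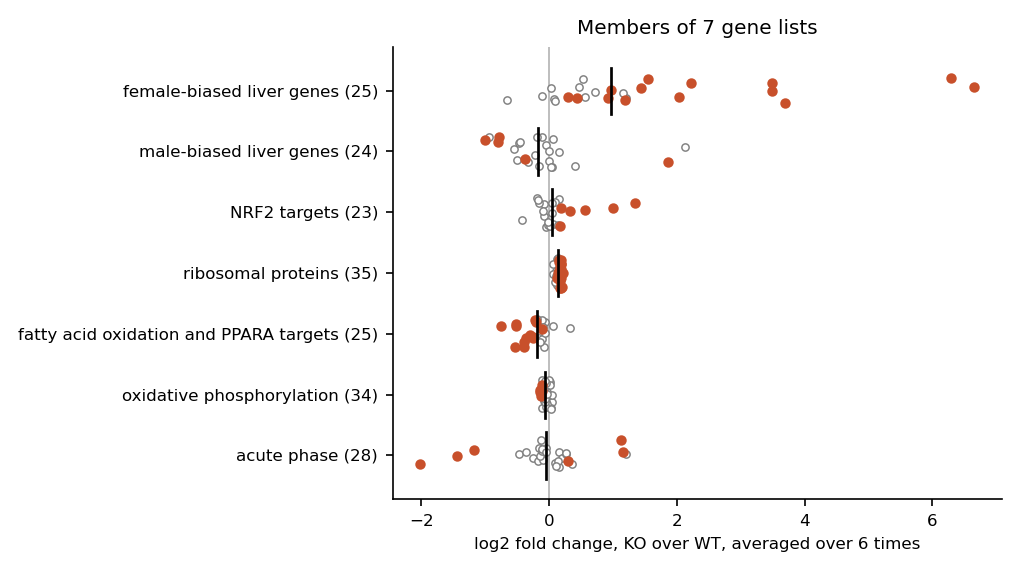
KO minus WT log2 fold change, averaged over the 6 times, of each measured member of 7 gene lists; filled points have an adjusted p under 0.05 and the bar marks the list's median. Female-biased genes have a median of 0.97 with 14 of 25 called higher, and fatty acid oxidation genes a median of -0.19 with 13 of 25 called lower.

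At single times, KO liver had the clock targets of the WT trough raised and those of the WT peak lowered. At ZT0, 10 of the 15 E-box targets were higher in KO and 0 lower, among them Dbp (log2 4.45, adjusted p = 0.0115), Per3 (3.09, adjusted p = 0.000851), Per1 (2.93, adjusted p = 0.00302) and Tef (1.85, adjusted p = 9.44e-05). Among genes with at least 5 CPM and not named so far, Ugt2b37, Hcn3 and Thrsp had the largest rises (2.34, 2.29 and 2.20) and Clic3, Spon2 and Atoh8 the largest falls (-1.60, -1.48 and -1.26). Thrsp, a lipogenic regulator, stood at 180.1 CPM ± 122 in WT and 826 ± 301 in KO (SD, n = 4 each, adjusted p = 0.00689). edgeR called 249 genes at ZT0, 158 higher and 91 lower. With total counts in place of TMM, which moved the median of all genes to -0.10 on the log2 scale, 110 were higher and 304 lower. With only the 8 libraries of ZT0 in the fit 0 genes were called by edgeR, with 1639 of 14054 at an unadjusted p under 0.05, while in the 48 libraries DESeq2 called 494. Dbp, Ugt2b37, Hcn3, Clic3, Spon2 and Atoh8 were not called when 1 of the 8 mice was left out (adjusted p = 0.0986, 0.0912, 0.238, 0.143, 0.109 and 0.123 at worst). Of the 8 mice, leaving out WT 45, 47 or 48 gave 148, 114 or 64 calls, and leaving out KO 41, 44 or 46 gave 629, 127 or 72.

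At ZT4 Per2 and Per3 were higher in KO, while Per1 did not pass (adjusted p = 0.114). Per2 stood at 9.40 CPM ± 3.82 in WT and 42.7 ± 6.75 in KO (SD, n = 4 each; log2 2.19, adjusted p = 0.00186), and Per3 rose by 1.72 (adjusted p = 0.0266). Nr1d1 was lower (-2.47, adjusted p = 0.0247). By the same rule Acot3, Ccrn4l and Tsku rose (2.20, 1.92 and 1.89) and Spon2, Rfx4 and Raet1c fell (-1.96, -1.61 and -1.53); Ccrn4l encodes the deadenylase nocturnin. Per3, Nr1d1, Acot3 and Raet1c were not called when 1 of the 8 mice was left out (adjusted p = 0.0959, 0.105, 0.136 and 0.108 at worst). Of the female-biased genes 9 were higher at ZT4, and of the heat shock genes 6. edgeR called 563 genes, 282 higher and 281 lower (385 and 168 with total counts). Leaving out WT mouse 3, 4 or 8 gave 229, 346 or 254 calls, and leaving out KO mouse 1, 6 or 7 gave 363, 332 or 203; without the 4 farthest libraries, all of other times, 1008 genes were called.

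At ZT8, the WT peak of Dbp, 6 of the 15 E-box targets were lower in KO and 1 higher, with Bhlhe41 at -3.24 (adjusted p = 0.000106), Nr1d1 at -3.02 (adjusted p = 0.00339) and Dbp at -2.99 (adjusted p = 0.0153). Slc34a2 (ENSMUSG00000029188, chromosome 5, 53429321 to 53462903), a sodium phosphate transporter gene, stood at 14.5 CPM ± 6.78 in WT and 198 ± 69.3 in KO (SD, n = 4 each; log2 3.76 ± 0.43 SE, adjusted p = 4.37e-07). Cdkn1a, the cell cycle inhibitor p21, rose by 2.80 (adjusted p = 0.000778), and Rgs16, a regulator of G protein signalling, changed by -4.22 ± 1.03 (SE, adjusted p = 0.00757). Nipal1 rose by 2.44, and Pcsk4 and Adora1 changed by -2.32 and -1.91. Dbp, Clock, Cry1 and Nipal1 were not called at ZT8 when 1 of the 8 mice was left out (adjusted p = 0.0664, 0.183, 0.0602 and 0.126 at worst). Of the cholesterol synthesis genes 9 were higher at ZT8 and 0 lower. Of the fatty acid oxidation genes 1 was higher and 8 lower. edgeR called 1167 genes, 561 higher and 606 lower (731 and 406 with total counts). The count was 613 without WT mouse 16 and 700 without KO mouse 9.

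At ZT12 edgeR called 1737 genes, 977 higher and 760 lower (674 and 936 with total counts). The count at ZT12 was above that at ZT8 there, but below it without the 4 farthest libraries (836 against 1635), with the length trend in the model (1219 against 1491) and from the 8 libraries of each time (231 against 1330). Of the E-box targets 10 were lower and 0 higher. The NAD synthesis gene Nampt, which peaks then in WT, stood at 221 CPM ± 18.8 in WT and 107 ± 15.7 in KO (SD, n = 4 each; log2 -1.05, adjusted p = 2.36e-05). Hsd3b5 and Elovl3, both on the male-biased list, rose (4.73 ± 1.33 and 3.78 ± 1.16 SE, adjusted p = 0.0154 and 0.0271) with a wide spread between KO mice. Hsd3b5 stood at 2.73 CPM ± 2.25 in WT and 72.7 ± 96.5 in KO (SD, n = 4 each). Without KO mouse 20 neither was called (adjusted p = 0.0892 and 0.138). Spon2 rose by 3.25 (adjusted p = 1.2e-06), having been lower in KO at ZT0 and ZT4. The phospholipid transporter gene Mfsd2a, Pcsk4 and Col27a1 changed by -2.83, -2.15 and -2.03. Of 35 ribosomal protein genes 10 were higher at ZT12, and 0 by edgeR without KO mouse 21, the mouse with the lowest length trend. Other mice moved this count as well. It was 2, 3 or 3 without WT mouse 17, 22 or 23, and 22 or 26 without KO mouse 18 or 24. Leaving out WT mouse 17 or 23 or KO mouse 21 gave 1103, 1036 or 1149 calls. Of the 4 farthest libraries 2 belong to ZT12.

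At ZT16, 11 of 20 heat shock, 9 of 24 unfolded protein response and 7 of 30 cell cycle genes were lower in KO and 0 higher. Hsp90aa1 and Hspa5, members of the first 2 lists, peaked in WT near that time. No list test was run at single times. Nr1d1 was higher (3.43, adjusted p = 0.00403), and Cyp2c55, Gstm3 and Rec8 rose by 1.80, 1.76 and 1.36. Cml5 and Chrna4 changed by -2.73 and -2.22, and Saa2 by -4.95 ± 1.44 (SE, adjusted p = 0.0342), with 2236 CPM ± 4356 in WT and 72.5 ± 40.6 in KO (SD, n = 4 each). This rests on WT mouse 29, without which the Saa2 change turned to 0.34 (adjusted p = 0.925). Without 1 of the 8 mice Cyp2c55, Rec8, Cml5 and Chrna4 at ZT16 were not called either (adjusted p = 0.0794, 0.0747, 0.0689 and 0.133 at worst). edgeR called 796 genes at ZT16, 385 higher and 411 lower (566 and 304 with total counts). Leaving out WT mouse 28 or 29 or KO mouse 25 or 31 gave 493, 398, 306 or 447 calls. Without the 4 farthest libraries 1230 were called.

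At ZT20 Dbp and Nr1d1 were higher in KO (3.73 and 3.25, adjusted p = 0.0239 and 0.0144). Atp6v0d2, Cyp2c55 and Gstm3 rose by 2.25, 2.20 and 1.68, and Chrna4, Clic3 and the nuclear receptor gene Ppard changed by -2.85, -1.76 and -1.44. edgeR called 156 genes, 96 higher and 60 lower (77 and 109 with total counts), and 327 by DESeq2. When 1 of the 8 mice was left out, Dbp, Nr1d1, Atp6v0d2, Cyp2c55, Gstm3, Chrna4, Clic3 and Ppard each missed the call in at least 1 fit (adjusted p = 0.0534 to 0.107 at worst). Leaving out WT mouse 33, 35 or 36 gave 48, 41 or 72 calls, and leaving out KO mouse 38 or 39 gave 52 or 59.

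**Figure D4:**
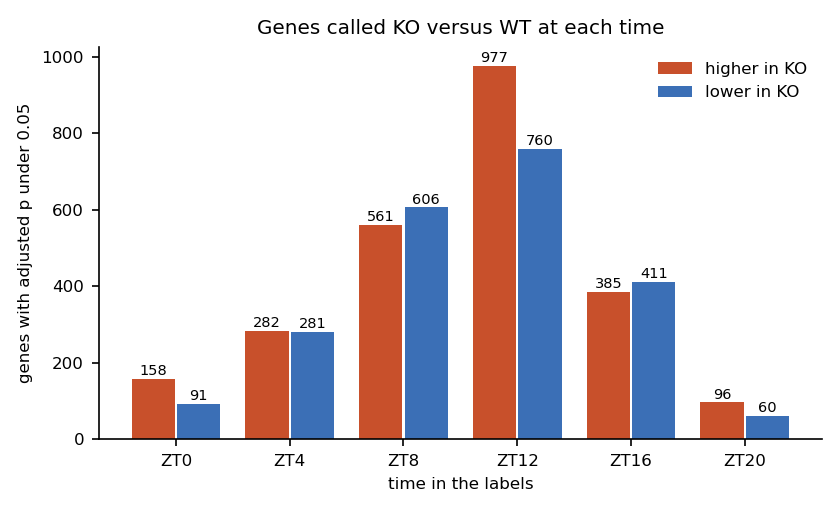
Number of genes with an adjusted p under 0.05 for KO against WT at each time (4 mice per genotype), higher in KO and lower in KO as separate bars from 0. The total is 1737 at ZT12 and 156 at ZT20. The order of the times changes without the 4 farthest libraries (836 at ZT12, 1635 at ZT8). Those 4 include KO mice 20 and 21 of ZT12 and no mouse of ZT8, so fewer KO mice were then compared at ZT12.

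Most genes that differed at a time were ones that cycled in WT, though the same WT mice enter both tests. At ZT8, for example, 965 of 1167 called genes (82.7%) had a WT rhythm, against 48.1% of all genes, and the share was 63.0% at ZT12 and 82.7 to 89.2% at the other times. In all 3459 genes were called at 1 or more times and 0 at every time, by edgeR.

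The difference between genotypes depended on the time for 3064 genes (20.7%, edgeR interaction), 2669 of which cycled in WT. All 15 E-box and all 5 REV-ERB-repressed genes were among them. Fgf1 (ENSMUSG00000036585, chromosome 18, 38998327 to 39089058), a growth factor gene, rose in WT from 101 CPM ± 8.77 at ZT4 to 255 ± 23.0 at ZT16 (SD, n = 4 each), while KO means stayed between 148 and 161 CPM (interaction adjusted p = 1.77e-08). Gys2 rose in WT from 99.9 CPM ± 9.60 at ZT0 to 354 ± 69.0 at ZT8 (SD, n = 4 each), while KO means stayed between 115 and 138 CPM (interaction adjusted p = 3.86e-08). Marveld1, Hnrnpl, Hsd3b7, which acts in bile acid synthesis, and Aqp8, a water channel, were also among the 10 smallest interaction p values (adjusted p = 1.77e-08, 1.77e-08, 7.59e-08 and 1.15e-07).

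In WT liver 7141 of 14836 genes (48.1%) had a 24 h rhythm, with 2801 having a fitted peak at least 1.5 times the trough and 1120 at least 2 times. Among genes with at least 5 CPM the largest amplitudes belonged to clock genes and to Serpina3c, Rgs16, Slc34a2, Loxl4 and Cdkn1a (log2 3.79, 2.71, 2.26, 2.08 and 1.90). WT peaks were spread over the day, with 1109 to 1254 genes in each 4 h bin. By a test that takes list members as independent, rhythms were more common than among other genes in 9 lists. These were all 20 heat shock genes (Fisher's exact test, adjusted p = 8.57e-06), 25 of 26 ribosome biogenesis genes (7.62e-06), 22 of 24 unfolded protein response genes (0.000112), and 21 of 23 fatty acid synthesis genes (0.000142). By the same test they were also all 15 E-box targets (0.000133), 17 of 20 glucose genes (0.00476), 23 of 30 cell cycle genes (0.00662), 25 of 34 oxidative phosphorylation genes (0.0113) and 20 of 26 amino acid genes (0.0147). Hsp90aa1 peaked at ZT 17.1 (4.19-fold) and Hspa5, the chaperone of the endoplasmic reticulum, at ZT 15.8 (2.57-fold). The lipid synthesis gene Lpin1 peaked at ZT 10.9 (5.96-fold), the pyruvate dehydrogenase kinase gene Pdk4 at ZT 21.1 (7.34-fold), the cyclin gene Ccnb2 at ZT 5.97 (8.19-fold) and the coumarin hydroxylase gene Cyp2a5 at ZT 11.6 (8.0-fold). With the length trend in the model 6 of the 34 oxidative phosphorylation genes were rhythmic in WT. Rhythms were called less often in 6 lists: male-biased (1 of 24, 5.11e-05), female-biased (3 of 25, 0.000943), acute phase (3 of 28, 0.000202), NRF2 targets (5 of 23, 0.032), Kupffer cell markers (1 of 13, 0.0119) and neutrophil markers (1 of 11, 0.032). Their median WT amplitudes were 0.302, 0.466, 0.253, 0.170, 0.0772 and 0.152 in that order, against 0.248 over WT-rhythmic genes. The list medians cover all members, most of them not called, while 0.248 covers genes chosen for a WT rhythm, so they are not alike. A fitted amplitude also grows with the spread between mice, so these medians do not tell why fewer members were called.

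In KO liver the 24 h rhythm across the mice was weaker. The amplitude of the 7141 WT-rhythmic genes had a median of 0.248 in WT and 0.104 in KO on the log2 scale, and was smaller in KO for 6878 (96.3%). Choosing genes by their WT rhythm raises their WT amplitudes, so part of this gap is built in. The median ratio of amplitudes was 0.402 (jackknife SE 0.0793), compared with 0.235 to 0.347 when the times of the KO mice were permuted, and 0.109 of the WT wave was kept in phase. With genes chosen in 2 WT mice per time and the amplitude measured in the other 2, the ratio was 0.325 and 0.362. Those choices held 2930 or 3788 genes, so these ratios cover fewer genes and WT mice than 0.402 and the permuted values do. Only 146 genes (0.984%) were called rhythmic in KO, 53 of them with a peak at least 1.5 times the trough, against 3205 at an unadjusted p under 0.05. They included Sap25 (amplitude 0.58, peak at ZT 5.57, adjusted p = 0.00474), Fgfr2 (0.32, adjusted p = 0.0144) and Serpina3c (3.50 ± 0.63 SE, peak at ZT 7.66, adjusted p = 0.0293). The ribosomal protein gene Rpl39 (0.25, peak at ZT 11.8, adjusted p = 0.0336) and the stress-responsive gene Ndrg1 (0.62, adjusted p = 0.0427) were also called. Of the 146 genes 82 were also rhythmic in WT, where 70.3 were expected of unrelated lists, and 35 peaked within 3 h in both. The 146 rested on single mice, since the count ran from 3 without KO mouse 14 of ZT8 to 473 without KO mouse 44 of ZT0. DESeq2 called 455, limma-voom 57, and 1 gene was called from the 24 KO libraries alone. With the length trend in the model 8 KO rhythms were called.

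Tested directly, the rhythm differed between genotypes for 3385 genes (22.8%), of which 3132 had the larger amplitude in WT and 253 in KO. The smallest p values outside the clock were those of Fgf1 (WT amplitude 0.72 ± 0.05 SE, KO 0.05, adjusted p = 1.57e-10), Marveld1 (0.72 ± 0.06 SE and 0.17, adjusted p = 1.41e-09) and the caspase gene Casp6 (0.85 ± 0.07 SE and 0.11, adjusted p = 2.84e-09). Next came Ivns1abp (0.44 and 0.20, adjusted p = 3.04e-09) and Pcbp4 (0.89 ± 0.07 SE and 0.16, adjusted p = 3.23e-09). Odc1, the first enzyme of polyamine synthesis, peaked in WT at ZT 15.3 with 173 CPM ± 15.8 at ZT16 against 53.8 ± 6.62 at ZT4 (SD, n = 4 each), and had an amplitude of 0.07 in KO (adjusted p = 1.45e-08). By list, the difference was called for 17 of 29 xenobiotic, 15 of 23 fatty acid synthesis, 14 of 20 glucose, 13 of 20 heat shock, 12 of 17 glucocorticoid, 15 of 26 ribosome biogenesis and 16 of 30 cell cycle genes. It was called for 0 of 35 ribosomal protein genes and 0 of 34 oxidative phosphorylation genes by edgeR, although 20 and 25 of them cycled in WT. Those WT counts were 6 and 6 with the length trend in the model, and 33 and 30 without the 4 farthest libraries. The median amplitudes of these 2 lists were 0.155 and 0.154 in WT and 0.179 and 0.0969 in KO. The amplitude was smaller in KO for 7 of 35 and 29 of 34 members. In KO itself a rhythm was called for 7 of 35 ribosomal protein genes and 0 of 34 oxidative phosphorylation genes, against 0.984% of all genes. KO mouse 21 of ZT12 had the highest ribosomal mean of all libraries (8.731 log2 CPM), and its part in these 7 calls was not tested. A difference that was not called does not show that these rhythms were kept. In simulated counts edgeR found 16% of rhythm differences at a log2 amplitude of 0.25. Far fewer genes changed there than in these data, and they were drawn from all genes, so 16% is not the power for these 2 lists.

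**Figure D5:**
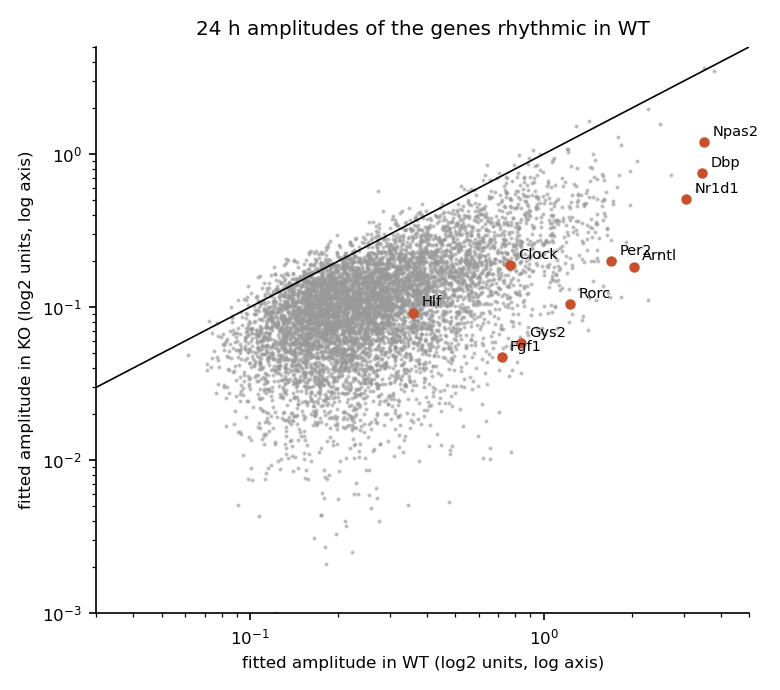
Fitted log2 amplitude in KO against that in WT for the 7141 genes with a WT rhythm (log axes), with the line of equality and 10 named genes. Of these genes 6878 (96.3%) lie below the line, and the medians are 0.248 in WT and 0.104 in KO. Choosing genes by their WT rhythm raises their WT amplitudes, so part of this gap is built in.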

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

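The tests of evenly spread phases and of a coherent shifted rhythm in this part were chosen only after the result was seen. Some values were marked by Dixon's test against the other 3 mice of their group: body weight of KO mouse 39 of ZT20 (23 g, low), the TMM factor of WT mouse 4 of ZT4 (1.0676), the share of counts in the 10 most abundant genes of KO mouse 31 of ZT16 (9.3777%, low), and the mean correlation of WT mouse 29 of ZT16 with its group (0.9853, low). Body weight of KO mouse 25 of ZT16 (29 g, high) was marked only because the other 3 mice all weighed 28 g. Arntl stood out in KO mouse 37 of ZT20 (17.616 CPM, high). Dbp stood out in WT mouse 48 of ZT0 (2.0793 CPM, high), WT mouse 8 of ZT4 (84.448 CPM, high), WT mouse 11 of ZT8 (136.62 CPM, low) and KO mouse 26 of ZT16 (43.463 CPM, high). The test was run on 108 groups of values (9 measures in 12 groups), and chance marks about 1 in 20.

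The KO minus WT difference depended on the time, by the interaction test, for 3064 genes, among them all 15 E-box targets and all 5 REV-ERB-repressed genes, and the 24 h rhythm differed between genotypes for 3385. Of the 20 genes with the largest average rises and falls, 2 depended on the time: Lpl (adjusted p = 0.0176) and Hspb1 (adjusted p = 0.00913). Of 291 other named genes 134 did. The 20 genes were chosen for the same sign at all 6 times, which leaves out genes whose change turns over with time. Some of the other named genes were chosen for small p values of the interaction or of the rhythm difference. The contrast between these counts is therefore partly built in, and no conclusion is drawn from it. Of all 1314 genes called on average, 384 depended on the time.

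Clock genes differed widely between KO mice killed at the same time, as the Dbp value of KO mouse 26 of ZT16 shows. A trend with transcript length was argued against, since a median of 97.733% of the variance of the clock genes was left after it was removed. Phases spread evenly over the cycle were argued against too: 79.363% of the variance of the KO positions lay along 1 axis, where random phases gave a mean of 62.2% (p = 0.0053 from 10000 random draws of the phases, which is not a permutation of mice). A leftover cycle whose phase differs between mice met its prediction, with a correlation of 0.812 over 190 gene pairs between the KO correlations and the cosine of the WT peak differences (permutation p = 0.0001; 0.861 in WT mice), and graded leftover activity of BMAL1 met its own, with a median correlation of 0.403 over 37 pairs of E-box targets with WT peaks at least 4 h apart (0.003 in WT mice, with a median cosine of 0.21 for their WT peaks). Both stay open, and as a hypothesis the KO mice may differ in how much BMAL1 activity is left, which reads over the deleted part of Arntl or BMAL1 protein would test and counts over the whole gene do not.

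The weak KO waves of the 20 clock genes lay on average -8.01 h from those of WT, and a coherent shifted rhythm was left open by a permutation p of 0.0591.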

How the results depend on the processing

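Leaving out the 4 libraries farthest from their groups and adding the length trend were chosen after the data were seen, and the cause of the moves below was not tested. No averaged change of a named gene reversed. At single times Saa2 did at ZT16, to 0.336 without WT mouse 29. For WT rhythms only the call was compared and not the peak time, so a reversal could not show. Of named genes called at a time, 14 of 51, 28 of 62, 40 of 86, 57 of 104, 28 of 55 and 8 of 32 kept the call whichever of the 8 mice was left out, at the 6 times in order. With total counts only the larger of the higher and lower sides turned at ZT0, ZT8, ZT12, ZT16 and ZT20. Counts over all genes not given here stayed within 1.5 times their main value. Counts of members called, 80 over 40 lists and 2 directions, moved further for 20 with body weight, 20 without the 4 libraries, 13 with the length trend, 3 with total counts only and 0 with DESeq2 size factors. Counts of WT-rhythmic members moved for 6 of 40 lists with the length trend and 5 without the 4 libraries. Averaged over times, 711 genes were called with body weight in the model. At ZT0 the count was 414 with total counts only, 161 with no filter, 494 by DESeq2, 145 with body weight, 74 without the 4 libraries, 119 with the length trend and 0 by edgeR from only the 8 libraries of ZT0. Without the 4 libraries it was 1008 at ZT4, 836 at ZT12, 1230 at ZT16 and 318 at ZT20; with the length trend 896 at ZT4; by DESeq2 327 at ZT20; and from only the 8 libraries of the time 231 at ZT12 and 274 at ZT20. Asking also for a 2-fold change left 80 averaged and 67, 128, 261, 309, 131 and 49 at the 6 times in order. Asking for a peak of 1.5 times the trough left 2801 WT and 53 KO rhythms. KO rhythms numbered 28 with no filter, 57 by limma-voom, 455 by DESeq2, 8 with the length trend and 1 from only the 24 KO libraries. Lists called numbered 0 with an estimated correlation, 5 by fry and 8 with a filter of 1 CPM in 4 libraries.

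With each mouse left out in turn, counts ran from 1112 to 1538 averaged, 64 to 629 at ZT0, 203 to 539 at ZT4, 613 to 981 at ZT8, 1036 to 2250 at ZT12, 306 to 696 at ZT16, 41 to 178 at ZT20, 2618 to 3326 for the interaction, 6603 to 7712 for WT rhythms, 3 to 473 for KO rhythms, 3053 to 3820 for the rhythm difference and 10 to 16 for lists. The amplitude ratio ran from 0.371 to 0.438, and was 0.325 and 0.362 with genes chosen in other WT mice. KO rhythms moved by over 1.5 times in 29 of 48 such fits. Of 331 named genes, averaged calls were lost for 13 with no filter, 8 by limma-voom, 1 with housing, 35 with body weight, 8 with cage as a block, 22 without the 4 libraries, 15 with the length trend and 21 when some mouse was left out. Those lost with the block include the averaged calls of Per3, Saa1, Hsd3b5, Saa2, Cspg5 and Ltf and the WT rhythm of Serpina3c. WT rhythms were lost for 7 with total counts only, 10 with no filter, 9 by limma-voom, 11 with cage as a block, 18 with the length trend, 27 when some mouse was left out and at most 3 otherwise. Total counts were matched before deposit, while genes detected ran from 17690 to 18774, so what depth limits in each library is not known.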

Other observations

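The length trend in the model was chosen only after the data were seen. The other tests in this part were planned. Asking that shared reads and body weight clear their limits by a jackknife SE was not part of the written predictions. By the written limits alone both would have been argued against. Alas1, the first enzyme of heme synthesis, peaked in WT at ZT 11.9 and Por, which passes electrons to cytochromes P450, at ZT 10.3. The cholesterol exporter gene Abcg5 peaked at ZT 7.71 and the fatty acid oxidation gene Cpt1a at ZT 8.0. The log2 amplitudes of these 4 genes were 1.60, 0.91, 0.77 and 0.58 in WT and 0.41, 0.26, 0.08 and 0.12 in KO (rhythm difference adjusted p = 0.00118, 1.43e-05, 1.14e-06 and 3.86e-06), and the processes they belong to were not tested by them. Rhythms of Rpl18 (peak at ZT 12.3) and Ndufb10 (ZT 12.6) did not pass the test of a difference (adjusted p = 0.686 and 0.364).

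Of 25 female-biased genes 14 were called higher in KO and 0 lower, while camera with an estimated correlation did not call the list (adjusted p = 0.284). Mice of the other sex were argued against, since Xist reached 0.53149 CPM at most in any library and 4 Y-linked genes summed to at least 134.5 CPM in each. Reads shared between paralogs were left open: the 12 members outside the 6 families had a median log2 fold change of 0.523 (jackknife SE 0.383), with Prlr, Trim24 and Cyp17a1 among those called higher. Lower body weight was left open too, since 94.158% of the list's median was kept with weight in the model, with a jackknife SE of 29.1%. The list mean and body weight had r = -0.141 and rho = -0.124 over the 24 KO mice (permutation p = 0.509 and 0.562, adjusted p = 0.655 and 0.704; r = -0.146 without 2), and r = -0.0915 and rho = -0.0809 over the 24 WT mice (permutation p = 0.669 and 0.704, adjusted p = 0.752 and 0.704; r = -0.0799 without 2). No biological explanation was tested.

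Of 35 ribosomal protein genes 18 were called slightly higher in KO and 0 lower. Relative to the median of all genes, at least 97.691% of the list's median was kept under the other 2 scalings. A change of scaling moves all genes nearly alike, so this test could hardly fail and does not decide on the scaling. The list's own median was 0.148 with TMM, 0.135 with total counts and 0.146 with DESeq2 size factors. A trend with transcript length was left open: 54.209% of the median was kept (jackknife SE 22.96%), from 0.148 to 0.08, and KO mouse 21 of ZT12 had both the lowest length trend and the highest ribosomal mean. No biological explanation was tested.

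Other splits of the mice were counted with the real one included. The averaged comparison, the interaction, the rhythm difference, WT rhythms and KO rhythms were reached in 1 of 60 splits each, with at most 4, 124, 58, 1228 and 1 calls in the others. ZT4, ZT8, ZT12, ZT16 and ZT20 were reached in 1 of 35 splits each, with at most 3, 0, 468, 4 and 0 in the others. Chance was not excluded at ZT0, where 2 of 35 splits gave as many calls (303 in the other), nor for the lists, where 32 of 60 splits gave 13 or more.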
